A study of Homo sapiens with 154 samples.

How the data were processed

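Whole blood of 27 patients with intracerebral hemorrhage was drawn within 24 h of onset (baseline), at 72 h and at 7 days, per the labels. Globin and ribosomal RNA were depleted and directional messenger RNA libraries made, and separate small RNA libraries were made from the same draws, per the labels' protocols. Each kind has 77 libraries (27, 26 and 24), and 23 patients have all 3 time points. The labels place patients in 2 sequencing batches, called A and B here; a patient lies in 1 batch only.

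Reads were checked with FastQC, trimmed with cutadapt and mapped to hg38, per the submitters' processing notes, which give no versions. The aligner, the counter and the annotation are not given in the sources used here. The deposited signal is 1 table of normalised values per kind, with 38349 genes and 912 microRNAs, the latter named as in MirGeneDB. How the authors scaled that deposited signal was worked out from the values: dividing each library by a single step of its values gave whole numbers for 100% of the values above 0 (tolerance 0.01 reads), and the implied library factors matched median-of-ratios factors with ratios from 1.0 to 1.0. The smallest recovered value above 0 was 1 read for genes and 2 for microRNAs.

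The recovered depth of the messenger RNA libraries ran from 51593 to 72427874 reads with a median of 28582839. A single baseline library of batch A held 51593 reads and 8537 genes with a read, so that 1 of its reads is worth 289.3 units; the second lowest held 15562819 reads. The small RNA libraries held 213075 to 27748043 reads with a median of 6870663 (9455477 in batch A and 2614009 in batch B), and 4 held fewer than 1000000. RPS29 took 1.98% to 46.1% of the reads of a messenger RNA library (median 20.7%), and Hsa-Mir-486_5p 11.1% to 59.4% of a small RNA library (median 28.3%, 22.2% in A and 43.1% in B).

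Time points were compared within patients by limma (lmFit, contrasts.fit and eBayes with a trend) on log2 of the deposited value plus 1, with time and patient as terms. Batch is constant within a patient and is removed by that block. Features with a mean value of at least 10 were tested (27864 genes and 263 microRNAs), p-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. The 3 comparisons were 72 h against baseline, 7 days against 72 h and 7 days against baseline. These choices, the lists and their wording, the gene-naming rule and most alternatives were fixed before the data were examined. The whole-number reads were found afterwards, so the edgeR quasi-likelihood test on them was added as an alternative, as were all fits without the shallow messenger RNA library or without the 4 shallowest small RNA libraries.

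The pairing comes from the patient numbers in the labels. For the 72 h columns of the messenger RNA table the patient was read from the number in the column name, because the labels spell the time differently there. It was checked on the correlation of whole libraries: the median r was 0.953 within patients and 0.932 between patients for messenger RNA, and 0.967 and 0.920 for microRNA. The closest library was of the same patient for 26 of 77 and 45 of 77 libraries, and 0 libraries were identical.

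Lists of 36 gene groups and 10 microRNA groups were written from general knowledge: azurophil, specific and gelatinase granules, secretory vesicles and their union as neutrophil degranulation; markers of mature and immature neutrophils, classical and non-classical monocytes, T, regulatory T, B, plasma, natural killer, dendritic, basophil and eosinophil cells, platelets and red cells. Further gene lists were T cell receptor signalling, MHC class II, globin, heme and iron, interferon, cytokine and NF-kB, IL-1 and inflammasome, Toll-like receptor, glucocorticoid, immediate early, cell cycle, circadian, complement, NADPH oxidase and extracellular trap, ribosomal protein, oxidative phosphorylation and brain genes. MicroRNA lists were the title microRNAs, myeloid, lymphocyte, erythroid, platelet, 14q32, inflammation, let-7, miR-17-92 and brain-enriched microRNAs. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. A preset correlation takes members to be nearly independent, so the estimated value stands beside each call it removes. Counts of called members are given over all genes and adjusted over the list alone.

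Named genes follow a rule: per comparison the 6 largest rises and 6 largest falls with a mean value of at least 50 and the same direction in 75% of the patients, up to 4 members of smallest p from each list that passed or held a call, and a fixed set of granule, acute-phase and heme genes with the title microRNAs. Genes that identify sex were left out of every named set. A direction in patients counts those with both time points.

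For each patient the change of the mean of the 151 degranulation genes was related to the change of each of 3 title microRNAs in each comparison (9 relations) by Pearson r and Spearman rho, with p from 100000 permutations, or exact under 10 patients. The family of 9 was adjusted by Benjamini-Hochberg.

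The methods were tested on simulated data with the same libraries and spread. With 200 of 27864 genes changed, limma found 28% of 1.5-fold and 52% of 2-fold changes from baseline to 7 days and called 4 unchanged genes; without the shallow library 40% and 63% were found with 7 unchanged genes called. From 72 h to 7 days 24% and 49% were found with 1 unchanged gene called. With 40 of 263 microRNAs changed, 30% and 70% were found from baseline to 7 days with 0 unchanged called. Of 200 random gene lists, 7 passed an unadjusted camera p of 0.05 there, but correlated members were not tested. Of 200 pairs with r of 0.6 (24 patients) 186 were found, and 6 of 200 unrelated.

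The alternatives tried were pseudocounts of 0.5 and 5, no filter and a filter of 50, TMM and upper-quartile scaling, no block, patient as a random effect, complete cases, each batch alone, only the libraries of both time points compared, array weights, the mature neutrophil score as a covariate, a fold threshold of 1.2, each patient left out, and the additions named above. Gene symbols matched the GRCh38.p14 gene table for 34838 of 38349 genes, and positions were taken from it. R 4.3.3, limma 3.58.1, edgeR 4.0.16, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Outcome and severity of the patients were not analysed here.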

Results

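Whole blood was sampled from 27 patients with intracerebral hemorrhage within 24 h of onset (baseline), at 72 h and at 7 days, per the labels. Messenger RNA and small RNA were sequenced in 77 libraries each: 27 at baseline, 26 at 72 h and 24 at 7 days. All 3 time points were present for 23 patients. The patients fell into 2 batches, named A (17, 17 and 14 libraries) and B (10, 9 and 10 libraries). Changes are log2 differences within patients tested with limma, unless another tool is named.

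At 72 h, transcripts of eosinophils and platelets rose. PRSS33, a serine protease of eosinophils, rose by 2.06 log2 (SE 0.409, limma adjusted p = 0.00486, higher in 22 of 26 patients), from a mean of 5.02 (SD 2.12, n = 27) to 7.06 (SD 1.53, n = 26). ALOX15, the lipoxygenase with which eosinophils make lipid mediators, rose by 1.84 (SE 0.406, adjusted p = 0.0143, higher in 19 of 26). OLIG2, a transcription factor of the eosinophil list, rose by 1.53 (SE 0.313, adjusted p = 0.00672, higher in 22 of 26). ITGA2B and ITGB3 encode the subunits of the platelet fibrinogen receptor and rose by 1.03 (SE 0.152, adjusted p = 0.000254, higher in 24 of 26) and 0.95 (SE 0.163, adjusted p = 0.00119, higher in 24 of 26). MYL9, the myosin light chain with which platelets change shape, rose by 1.41 (SE 0.299, adjusted p = 0.00923, higher in 25 of 26). Means lay above 0 in both batches: PRSS33 2.51 in A (2.18 without the shallow library described below) and 1.24 in B, ITGA2B 1.04 (0.99) and 1.02, MYL9 1.54 (1.06) and 1.19.

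Platelet genes had the smallest camera p of any list at 72 h. Of 33 measured, 33 lay above 0, the mean change was 0.71, and 10 rose and 0 fell (25 and 0 adjusted over the list alone); the camera adjusted p was 2.15e-24, and adjusted p = 0.272 with an estimated correlation. By fry the adjusted p was 0.00288. Eosinophil genes (17 measured) averaged 0.87 with 4 up and 0 down (10 and 0 adjusted over the list alone, camera adjusted p = 7.24e-10, adjusted p = 0.362 with an estimated correlation). NRGN, a calmodulin-binding protein of platelets, rose by 0.82 (SE 0.148, adjusted p = 0.00213, higher in 24 of 26). SMIM1, which carries the Vel blood group of red cells, rose by 1.30 (SE 0.272, adjusted p = 0.00842, higher in 23 of 26). MAP1A, a microtubule-associated protein, and H1-10, a linker histone, rose by 1.31 (SE 0.299, adjusted p = 0.0214, higher in 24 of 26) and 1.18 (SE 0.29, adjusted p = 0.0331, higher in 25 of 26).

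The largest falls at 72 h lay outside the granule genes. DAAM2, a formin that organises actin, fell by 1.25 (SE 0.258, adjusted p = 0.00735, lower in 24 of 26 patients). GRAMD1C, a sterol transporter, fell by 0.65 (SE 0.127, adjusted p = 0.00466, lower in 25 of 26), and LRRN1, a leucine-rich repeat membrane protein, by 0.72 (SE 0.144, adjusted p = 0.00567, lower in 21 of 26). SH3PXD2B, a podosome scaffold, fell by 0.71 (SE 0.175, adjusted p = 0.0334, lower in 21 of 26). TTC26 and NSUN7 fell by 0.63 (adjusted p = 0.0254, lower in 22 of 26) and 0.62 (adjusted p = 0.0303, lower in 20 of 26). IL18R1, a receptor subunit for interleukin 18, fell by 1.04 (adjusted p = 0.0228, lower in 19 of 26). NFKB2, the p100 subunit of NF-kB, went the other way and rose by 0.63 (SE 0.128, adjusted p = 0.00672, higher in 25 of 26).

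In all, 189 genes rose and 18 fell at 72 h at an adjusted p under 0.05, of 27864 tested. That count depended on a single shallow library, a baseline library of batch A with 51593 reads. Without it 1202 genes rose and 373 fell, and all 207 genes called with it were among them. The median change of all genes moved from -0.03 to -0.17 when it was left out. Rescaling by TMM factors moved the median to 0.09 and gave 163 up and 9 down. The edgeR quasi-likelihood test on the recovered reads called 1437 up and 433 down. Within batch A alone 20 genes rose and 1 fell, and within batch B 1 gene was called, DEFA3. Without the patient as a block 22 genes were called.

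T and B cell lists were higher at 72 h. T cell genes (24 measured) averaged 0.43, with 1 up and 0 down (8 and 0 adjusted over the list alone, camera adjusted p = 1.27e-07, adjusted p = 0.401 with an estimated correlation). BCL11B, a transcription factor of the T cell lineage, rose by 0.52 (SE 0.136, adjusted p = 0.047, higher in 19 of 26). T cell receptor signalling genes (30 measured) averaged 0.33 with 2 up, SLA2 and GRAP2, and 0 down (4 and 0 adjusted over the list alone, camera adjusted p = 7.45e-07, adjusted p = 0.362 with an estimated correlation). SLA2, an adaptor that restrains receptor signalling, rose by 0.45 (SE 0.105, adjusted p = 0.0244, higher in 22 of 26). B cell genes (20 measured) averaged 0.47 with 0 called by limma over all genes (8 up and 0 down adjusted over the list alone, camera adjusted p = 2.86e-06, adjusted p = 0.436 with an estimated correlation). CD79B, a signalling chain of the B cell receptor, was 0.57 higher (adjusted p = 0.0521, higher in 21 of 26) and passed without the shallow library (0.60, adjusted p = 0.0102). The natural killer and cytotoxic list (26 measured) averaged 0.15 with 0 called and did not pass (camera adjusted p = 0.294), and its mean was 0 without that library.

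The same held for monocyte, energy and translation lists at 72 h. Non-classical monocyte genes (16 measured) averaged 0.51 with 0 called over all genes (7 up and 0 down adjusted over the list alone, camera adjusted p = 9.89e-05, adjusted p = 0.436 with an estimated correlation). Classical monocyte genes (22 measured) averaged 0.29, with 0 called (5 up and 0 down adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.564 with an estimated correlation). Cytosolic ribosomal protein genes (54 measured) all lay above 0, averaging 0.50 with 0 called (10 up and 0 down adjusted over the list alone, camera adjusted p = 1.05e-13, adjusted p = 0.436 with an estimated correlation). Oxidative phosphorylation genes (46 measured) averaged 0.46; NDUFV1, a subunit of complex I, rose by 0.45 (SE 0.114, adjusted p = 0.0421, higher in 19 of 26) and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 3.81e-11, adjusted p = 0.436 with an estimated correlation). MHC class II genes (10 measured) averaged 0.46 with 0 called (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.000749, adjusted p = 0.436 with an estimated correlation).

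Neutrophil lists lay on opposite sides of the other genes at 72 h, with few members called. CEBPE, the transcription factor that drives granule formation in myelocytes, rose by 0.96 (SE 0.234, adjusted p = 0.0312, higher in 23 of 26). Immature neutrophil genes (25 measured) averaged 0.40, with CEBPE the only call (6 up and 1 down adjusted over the list alone, camera adjusted p = 0.000535, adjusted p = 0.556 with an estimated correlation). Mature neutrophil genes (24 measured) averaged -0.19 with 0 called (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.58 with an estimated correlation). Neither list passed camera in batch A (means 0.23 and -0.11, adjusted p = 0.141 and 0.0897), where the immature mean was -0.05 without the shallow library. Both passed in batch B (0.69 and -0.33, adjusted p = 3.08e-13 and 1.28e-06). Azurophil granule genes (31 measured) averaged 0.52 with 2 up and 0 down (12 and 0 adjusted over the list alone, camera adjusted p = 1.07e-09, adjusted p = 0.362 with an estimated correlation). MPO, the granule peroxidase, was 0.87 higher (SE 0.292, adjusted p = 0.146, higher in 17 of 26), ELANE, neutrophil elastase, 0.86 higher (SE 0.297, adjusted p = 0.154, higher in 18 of 26), and neither passed. MMP9, gelatinase B, was 0.53 lower (SE 0.229, adjusted p = 0.226, lower in 17 of 26). DEFA3, an azurophil defensin whose reads are shared with the near-identical DEFA1 copies and are uncertain for that reason, rose by 1.57 (SE 0.336, adjusted p = 0.0102, higher in 22 of 26).

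Other lists past camera at 72 h held few called genes. NADPH oxidase and trap genes (19 measured) averaged 0.30 with 0 called (5 up and 0 down adjusted over the list alone, camera adjusted p = 0.00453, adjusted p = 0.556 with an estimated correlation). Cytokine and NF-kB genes (25 measured) averaged 0.19 with 1 up and 0 down (4 and 0 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.556 with an estimated correlation). Regulatory T cell genes (13 measured) averaged 0.25 with 0 called by either count (camera adjusted p = 0.0242, adjusted p = 0.543 with an estimated correlation). Plasma cell genes (13 measured) averaged 0.27 with 0 called (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.0261, adjusted p = 0.556 with an estimated correlation). Gelatinase granule genes (32 measured) averaged 0.15 with 3 up and 0 down (5 and 0 adjusted over the list alone, camera adjusted p = 0.00453, adjusted p = 0.58 with an estimated correlation). Globin genes (10 measured) averaged -0.88 with 0 called (camera adjusted p = 0.000373, adjusted p = 0.543 with an estimated correlation), -0.07 in batch A (adjusted p = 0.668, mean -0.54 without the shallow library) and -2.34 in batch B. Heme and iron genes (40 measured) averaged 0.28 with 0 called (1 up and 0 down adjusted over the list alone, camera adjusted p = 0.000751, adjusted p = 0.556 with an estimated correlation), and HMOX1, which degrades heme, was 0.85 higher (SE 0.298, adjusted p = 0.161, higher in 21 of 26) and rose without the shallow library (0.53, adjusted p = 0.0305). Glucocorticoid-responsive genes (23 measured) averaged -0.13 with 0 called (0 up and 5 down adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.556 with an estimated correlation). FKBP5, a chaperone induced by glucocorticoids, was 0.72 lower (SE 0.231, adjusted p = 0.13, lower in 17 of 26) and fell without the shallow library (-0.74, adjusted p = 0.0491). IRF5, which relays Toll-like receptor signals, rose by 0.49 (SE 0.112, adjusted p = 0.0227, higher in 22 of 26) and was the only call of its list (27 measured, mean 0.22, 4 up and 0 down adjusted over the list alone, camera adjusted p = 0.00239, adjusted p = 0.556 with an estimated correlation).

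Leaving out the shallow library lowered the means of these lists at 72 h, while in most of them more members passed over all genes. Without it T cell genes averaged 0.26 (6 up, 0 down), T cell receptor signalling genes 0.21 (6 up, 0 down), and B cell genes 0.27 (4 up, 0 down). Non-classical monocyte genes averaged 0.33 (2 up, 0 down) and classical monocyte genes 0.15 (2 up, 0 down). Ribosomal protein genes averaged 0.34 (3 up), oxidative phosphorylation genes 0.25 (5 up), and MHC class II genes 0.34 (1 up). Platelet genes averaged 0.55 (19 up) and eosinophil genes 0.65 (9 up). Immature neutrophil genes averaged 0.24 with 1 up and 0 down by either count, azurophil granule genes 0.37 (6 up), gelatinase granule genes 0.05 (4 up) and mature neutrophil genes -0.27 (2 down). Heme and iron genes averaged 0.11 (3 up), Toll-like receptor genes 0.09 (6 up), globin genes -1.21 (1 down) and glucocorticoid-responsive genes -0.25 (2 down), the last no longer past camera (adjusted p = 0.068). Cytokine genes averaged 0.06 (4 up), plasma cell genes 0.10 (1 up), regulatory T cell genes 0.11 and NADPH oxidase and trap genes 0.22, the last of these with 0 up adjusted over the list alone. Secretory vesicle genes, not past camera with all libraries (mean 0.11, adjusted p = 0.111), passed there with a mean of 0.02 (adjusted p = 0.0285). None of them passed with an estimated correlation there either. Within batch B alone the gelatinase granule (mean 0.04, camera adjusted p = 0.387), classical monocyte (0.07, 0.505), MHC class II (0.20, 0.134) and Toll-like receptor lists (0.09, 0.0983) did not pass at 72 h. Nor did the cytokine (0.04, 0.458), regulatory T cell (0.10, 0.234) and plasma cell lists (0.15, 0.141).

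At 7 days, genes of young neutrophils stood far above baseline. LTF, the iron-binding lactoferrin of specific granules, rose by 1.92 (SE 0.269, adjusted p = 7.63e-06, higher in 22 of 24 patients), from 9.98 (SD 1.26, n = 27) to 11.85 (SD 2.27, n = 24). MPO rose by 1.87 (SE 0.302, adjusted p = 0.000105, higher in 23 of 24) and ELANE by 1.69 (SE 0.306, adjusted p = 0.000636, higher in 21 of 24). LCN2, which withholds iron from bacteria, rose by 1.80 (SE 0.306, adjusted p = 0.000247, higher in 19 of 24), and MMP8, the neutrophil collagenase, by 1.43 (SE 0.309, adjusted p = 0.00506, higher in 20 of 24). CEBPE, which is also in the eosinophil list, rose by 1.68 (SE 0.241, adjusted p = 1.3e-05, higher in 23 of 24). OLFM4, a specific granule protein of a neutrophil subset, rose by 1.64 (SE 0.349, adjusted p = 0.00442, higher in 18 of 24). By batch the changes were 1.02 in A and 3.25 in B for LTF, 1.27 and 2.76 for MPO, and 0.84 and 2.80 for OLFM4. Those of A without the shallow library were 1.10 (adjusted p = 0.0196), 0.91 (adjusted p = 0.073) and 0.48 (adjusted p = 0.268). A test of the batch by time interaction called 0 genes at 7 days, with or without that library. DEFA3, uncertain because of the DEFA1 copies, rose by 2.71 (SE 0.346, adjusted p = 1.46e-06, higher in 22 of 24).

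**Figure D1:**
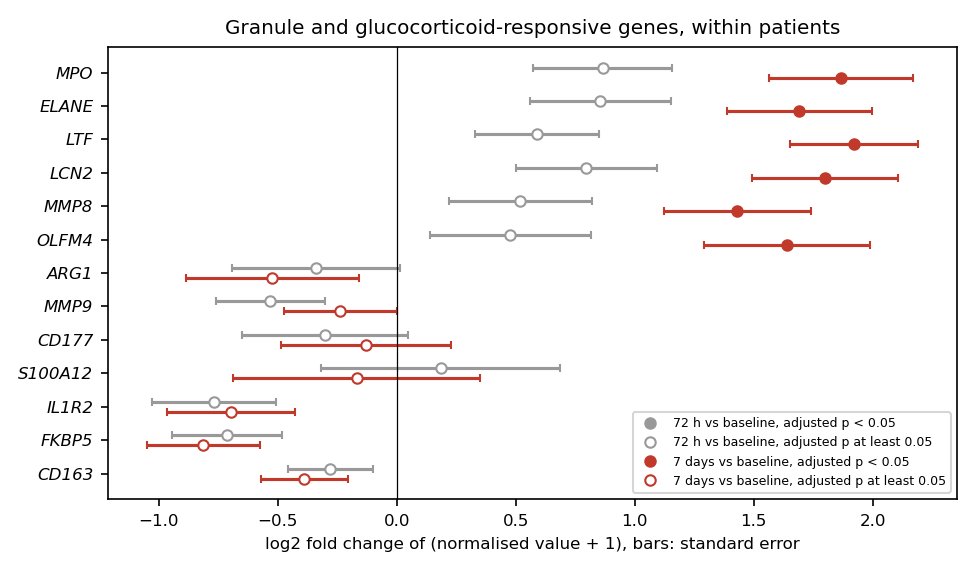
Log2 changes of granule and glucocorticoid-responsive genes within patients at 72 h and 7 days against baseline, with standard errors. Filled points passed an adjusted p of 0.05 in limma.

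By list, immature neutrophil genes averaged 1.10 at 7 days, with 17 of 25 up and 0 down (18 and 0 adjusted over the list alone, camera adjusted p = 2.25e-23, and adjusted p = 0.0337 with an estimated correlation); the mean was 0.73 in batch A (0.43 without the shallow library) and 1.64 in batch B. Azurophil granule genes averaged 0.82, all 31 above 0, with 11 up and 0 down (18 and 0 adjusted over the list alone, camera adjusted p = 7.54e-17, and adjusted p = 0.0436 with an estimated correlation). CTSG, the granule protease cathepsin G, rose by 1.90 (SE 0.359, adjusted p = 0.00104, higher in 20 of 24). Specific granule genes (27 measured) averaged 0.60 with 11 up and 0 down (13 and 1 adjusted over the list alone, camera adjusted p = 5.35e-08, adjusted p = 0.209 with an estimated correlation). CAMP, the precursor of the antimicrobial peptide LL-37, rose by 1.53 (SE 0.318, adjusted p = 0.00348, higher in 18 of 24). Gelatinase granule genes (32 measured) averaged 0.04, with 3 up and 1 down (4 and 2 adjusted over the list alone, camera adjusted p = 0.717), 0.15 in batch A (-0.02 without the shallow library) and -0.13 in batch B. Secretory vesicle genes (63 measured) averaged -0.08 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.00469, adjusted p = 0.768 with an estimated correlation); without the shallow library 3 fell. Mature neutrophil genes averaged -0.46 with 0 of 24 above 0 and 0 up and 2 down (0 and 16 adjusted over the list alone, camera adjusted p = 8e-14, adjusted p = 0.209 with an estimated correlation). BASP1, a membrane-bound signalling protein of mature neutrophils, fell by 0.58 (SE 0.137, adjusted p = 0.0121, lower in 19 of 24).

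Eosinophil and platelet genes stayed high at 7 days. PRSS33 rose by 2.78 (SE 0.422, adjusted p = 3.35e-05, higher in 22 of 24), ALOX15 by 2.52 (SE 0.419, adjusted p = 0.000176, higher in 22 of 24) and CLC, the Charcot-Leyden crystal protein, by 1.90 (SE 0.384, adjusted p = 0.00245, higher in 21 of 24). PTGDR2, the prostaglandin D2 receptor of eosinophils and basophils, rose by 1.43 (SE 0.247, adjusted p = 0.00032, higher in 20 of 24). Eosinophil genes averaged 1.25, all 17 above 0, with 10 up and 0 down (13 and 0 adjusted over the list alone, camera adjusted p = 1e-18, and adjusted p = 0.0337 with an estimated correlation); the mean was 1.40 in batch A (1.02 without the shallow library) and 1.02 in batch B. ITGA2B rose by 1.28 (SE 0.156, adjusted p = 1.42e-06, higher in 23 of 24), ITGB3 by 1.12 (SE 0.168, adjusted p = 2.67e-05, higher in 21 of 24) and ITGB5, another integrin, by 0.70 (SE 0.108, adjusted p = 3.96e-05, higher in 23 of 24). Platelet genes averaged 0.88, all 33 above 0, with 17 up and 0 down (32 and 0 adjusted over the list alone, camera adjusted p = 2.02e-34, and adjusted p = 0.0337 with an estimated correlation); the mean was 1.06 in A (0.79 without the shallow library) and 0.61 in B, and 25 rose without the shallow library.

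Plasma cell genes rose with them. MZB1, a chaperone of immunoglobulin assembly, rose by 2.15 (SE 0.294, adjusted p = 5.43e-06, higher in 21 of 24), and IGKC, the kappa light chain constant region, by 2.08 (SE 0.389, adjusted p = 0.000967, higher in 21 of 24). JCHAIN, which joins IgA and IgM, rose by 1.74 (SE 0.371, adjusted p = 0.00447, higher in 22 of 24) and IRF4, a driver of plasma cell fate, by 0.86 (SE 0.149, adjusted p = 0.000357, higher in 21 of 24). ITM2C of the dendritic list rose by 1.01 (SE 0.162, adjusted p = 0.000103, higher in 23 of 24). Plasma cell and plasmablast genes (13 measured) averaged 0.87 with 7 up and 0 down (8 and 0 adjusted over the list alone, camera adjusted p = 1.33e-10, and adjusted p = 0.0337 with an estimated correlation); the mean was 0.98 in batch A (0.69 without the shallow library) and 0.70 in batch B. B cell genes averaged 0.55 with 2 up, CD79A and CD79B, and 0 down (13 and 0 adjusted over the list alone, camera adjusted p = 2.31e-08, adjusted p = 0.209 with an estimated correlation); without the shallow library 7 rose and the adjusted p with an estimated correlation was 0.0275. CD79B rose by 0.77 (SE 0.155, adjusted p = 0.00254, higher in 20 of 24). H3C14, a replication-dependent histone whose reads are shared with its near-identical copy H3C15 and are uncertain, rose by 2.08 (SE 0.264, adjusted p = 1.46e-06, higher in 22 of 24).

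**Figure D2:**
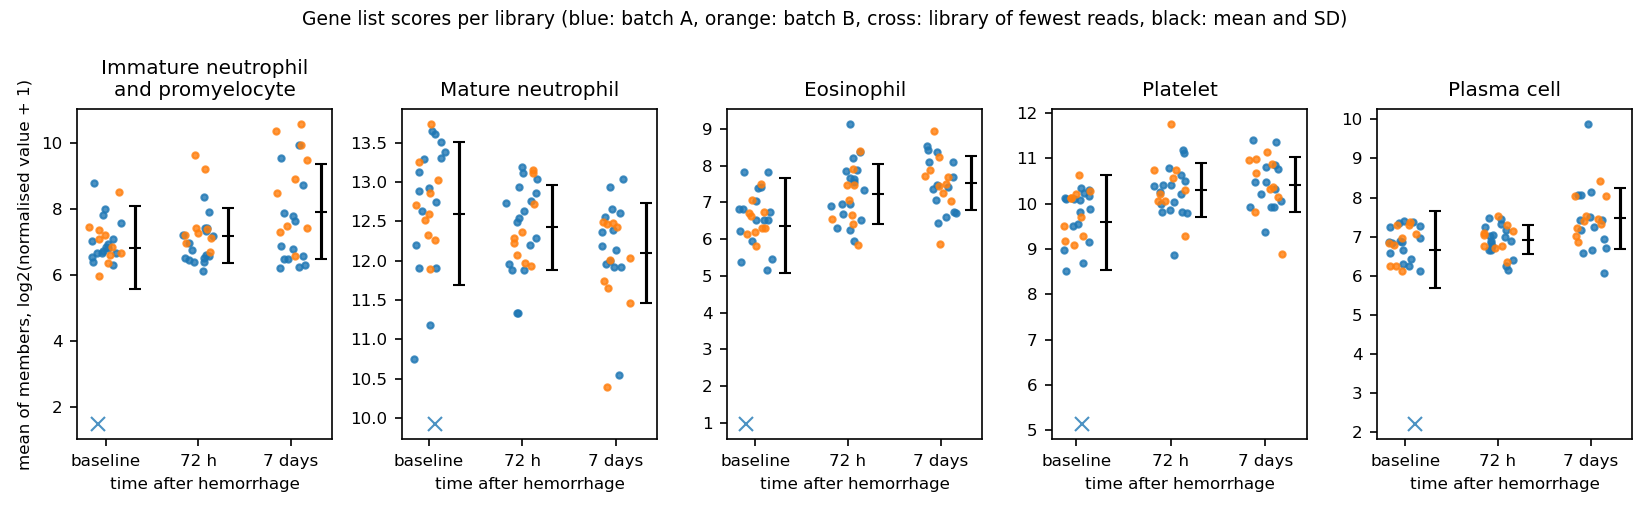
Mean log2 value of the members of 5 gene lists in each library at baseline, 72 h and 7 days. Blue marks batch A, orange batch B, the cross the shallow library, and black the mean and SD.

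T cell genes averaged 0.44 at 7 days with 3 up and 0 down (8 and 0 adjusted over the list alone, camera adjusted p = 5.35e-08, adjusted p = 0.209 with an estimated correlation). CD27, a costimulatory receptor, rose by 0.56 (SE 0.119, adjusted p = 0.00429, higher in 21 of 24), CD6 by 0.50 (SE 0.127, adjusted p = 0.0209, higher in 18 of 24) and LCK, the kinase that starts T cell receptor signalling, by 0.47 (SE 0.137, adjusted p = 0.0496, higher in 17 of 24). T cell receptor signalling genes averaged 0.31 with 3 up and 0 down (4 and 0 adjusted over the list alone, camera adjusted p = 3.35e-05, adjusted p = 0.241 with an estimated correlation). SLA2 rose by 0.60 (SE 0.109, adjusted p = 0.000619, higher in 23 of 24). Regulatory T cell genes (13 measured) averaged 0.27 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.0301, adjusted p = 0.385 with an estimated correlation). Natural killer and cytotoxic genes (26 measured) averaged 0.18 with 0 called by either count, and the list itself did not pass (camera adjusted p = 0.266).

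Non-classical monocyte genes averaged 0.58 at 7 days with 3 up and 0 down (6 and 0 adjusted over the list alone, camera adjusted p = 3.1e-05, adjusted p = 0.209 with an estimated correlation). C1QC, a subunit of the complement starter C1q, rose by 1.02 (SE 0.278, adjusted p = 0.0341, higher in 17 of 24) and RHOC, a regulator of cell movement, by 1.06 (SE 0.294, adjusted p = 0.0393, higher in 19 of 24). Classical monocyte genes averaged 0.13 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.315). MHC class II genes averaged 0.57 with 1 up, HLA-DRB1, and 0 down (5 and 0 adjusted over the list alone, camera adjusted p = 3.44e-05, adjusted p = 0.209 with an estimated correlation). HLA-DRB1 rose by 0.64 (SE 0.16, adjusted p = 0.0197, higher in 17 of 24), and its reads may be shared with other HLA-DRB genes, which leaves it uncertain. Dendritic cell genes (16 measured) had a mean of 0.27 and a median of 0.03, with 2 up and 0 down (6 and 0 adjusted over the list alone, camera adjusted p = 0.0355, adjusted p = 0.455 with an estimated correlation). Basophil and mast cell genes (14 measured) averaged 0.41 with 1 up and 0 down (4 and 0 adjusted over the list alone, camera adjusted p = 0.00495, adjusted p = 0.385 with an estimated correlation).

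Some growth and translation genes rose at 7 days. AURKB, a mitotic kinase, rose by 0.87 (SE 0.204, adjusted p = 0.0117, higher in 19 of 24) and ZWINT, a kinetochore protein, by 0.997 (SE 0.241, adjusted p = 0.014, higher in 18 of 24). Cell cycle genes (32 measured) averaged 0.36 with 4 up and 0 down (9 and 0 adjusted over the list alone, camera adjusted p = 2.42e-05, adjusted p = 0.381 with an estimated correlation). RPL18, a protein of the large ribosomal subunit, rose by 0.63 (SE 0.146, adjusted p = 0.00959, higher in 19 of 24). Ribosomal protein genes averaged 0.58 with 8 up and 0 down (28 and 0 adjusted over the list alone, camera adjusted p = 1.5e-18, adjusted p = 0.222 with an estimated correlation), and 13 rose without the shallow library. Oxidative phosphorylation genes averaged 0.47 with 4 up and 0 down (11 and 0 adjusted over the list alone, camera adjusted p = 3.08e-11, adjusted p = 0.318 with an estimated correlation), and 14 rose without the shallow library. NDUFV1 rose by 0.58 (SE 0.118, adjusted p = 0.00237, higher in 20 of 24).

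The receptor subunits IL18R1, IL18RAP and IL1RAP fell at 7 days, and IL1R2 did not pass. IL18R1 fell by 1.11 (SE 0.248, adjusted p = 0.0069, lower in 20 of 24), IL18RAP by 0.83 (SE 0.225, adjusted p = 0.0317, lower in 17 of 24) and IL1RAP, the shared signalling chain of the IL-1 family, by 0.86 (SE 0.182, adjusted p = 0.00415, lower in 19 of 24). The IL-1 family and inflammasome list (21 measured) averaged -0.21 with 0 up and 3 down (0 and 3 adjusted over the list alone, camera adjusted p = 0.000756, adjusted p = 0.381 with an estimated correlation). PFKFB2, which raises glycolysis, fell by 1.06 (SE 0.257, adjusted p = 0.0147, lower in 19 of 24), VNN3, a pantetheinase relative, by 0.90 (SE 0.176, adjusted p = 0.00161, lower in 22 of 24), and SLC11A1, a metal transporter of phagosomes, by 0.61 (SE 0.169, adjusted p = 0.0395, lower in 21 of 24). DAAM2 fell by 1.10 (SE 0.266, adjusted p = 0.0137, lower in 19 of 24). TCTEX1D4, a dynein light chain relative, and CNTNAP3, a contactin-associated protein, fell by 0.90 (SE 0.174, adjusted p = 0.00151, lower in 21 of 24) and 0.86 (SE 0.188, adjusted p = 0.00545, lower in 18 of 24). FKBP5 was 0.81 lower (SE 0.238, adjusted p = 0.0504, lower in 19 of 24) and fell without the shallow library (adjusted p = 0.0211). The glucocorticoid response list (23 measured) averaged -0.17 with 0 called (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.000756, adjusted p = 0.381 with an estimated correlation).

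Stimulus and heme lists were mixed at 7 days. NFKB2 rose by 0.46 (SE 0.132, adjusted p = 0.0453, higher in 20 of 24), and the cytokine and NF-kB list (25 measured) averaged 0.08 with that 1 call up and 0 down (1 and 0 adjusted over the list alone, camera adjusted p = 0.717). IRF5 rose by 0.42 (SE 0.116, adjusted p = 0.0375, higher in 17 of 24); Toll-like receptor genes (27 measured) averaged 0.05 with 1 up and 0 down (5 and 1 adjusted over the list alone, camera adjusted p = 0.876). Immediate early genes (29 measured) averaged 0.06 while camera placed the list down (adjusted p = 0.842), with MYC up by 0.47 (SE 0.13, adjusted p = 0.0393, higher in 19 of 24) and 0 down (1 and 2 adjusted over the list alone). Complement genes (27 measured) averaged 0.08, again with camera placing the list down (adjusted p = 0.842), and 1 rose and 0 fell (1 and 0 adjusted over the list alone). Circadian genes (17 measured) averaged 0.25 with 0 called (1 up and 0 down adjusted over the list alone, camera adjusted p = 0.0394, adjusted p = 0.572 with an estimated correlation). Heme and iron genes (40 measured) averaged 0.30 with 2 up, including granule LTF, and 1 down (3 and 1 adjusted over the list alone, camera adjusted p = 0.00328, adjusted p = 0.533 with an estimated correlation). HMOX1 was 0.72 higher (SE 0.307, adjusted p = 0.226, higher in 17 of 24), and CD163, the hemoglobin scavenger receptor, 0.39 lower (SE 0.184, adjusted p = 0.285, lower in 17 of 24).

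Several lists had unlike means in the batches at 7 days. Globin genes (10 measured) averaged -0.70 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.00252, adjusted p = 0.447 with an estimated correlation), but the mean was 0.21 in batch A (-0.31 without the shallow library) and -2.10 in batch B. HBA2, whose reads are shared with HBA1 and are uncertain, was 0.67 lower (SE 0.449, adjusted p = 0.481, lower in 12 of 24), 0.22 higher in A (0.01 lower without the shallow library) and 2.03 lower in B; globin transcripts had been depleted before sequencing. Interferon-stimulated genes (40 measured) averaged 0.14 with 0 called by either count (camera adjusted p = 0.61), 0.49 in A (camera adjusted p = 7.7e-05) and -0.37 in B (camera adjusted p = 2.5e-07). The mean in A was 0.22 without the shallow library (camera adjusted p = 9.47e-06). Erythroid genes (49 measured) averaged -0.02 with 0 called by either count (camera adjusted p = 0.657), 0.16 in A (adjusted p = 0.435, mean -0.10 without the shallow library) and -0.29 in B (adjusted p = 0.00371). ALAS2, the enzyme that starts heme synthesis in red cells, was 0.53 higher (SE 0.25, adjusted p = 0.288, higher in 16 of 24). NADPH oxidase and neutrophil extracellular trap genes (19 measured) had a mean of 0.47 and a median of 0.09, with 5 up and 0 down (6 and 0 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.385 with an estimated correlation). Brain-derived transcripts (17 measured) had a mean of 0.14 and a median of -0.10 with 2 up and 0 down (3 and 0 adjusted over the list alone, camera adjusted p = 0.398). ENO2, a neuronal enolase also made by platelets, rose by 0.99 (SE 0.261, adjusted p = 0.0262, higher in 19 of 24).

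Without the shallow library most of these means at 7 days were lower too. Immature neutrophil genes then averaged 0.93 (18 up, 1 down), azurophil granule genes 0.67 (15 up), and specific granule genes 0.43 (12 up, 2 down). Gelatinase granule genes averaged -0.07 (4 up, 2 down), secretory vesicle genes -0.18 (camera adjusted p = 0.0795) and mature neutrophil genes -0.55 (10 down). Eosinophil genes averaged 1.02 (12 up), platelet genes 0.71, plasma cell genes 0.70 (7 up) and B cell genes 0.34. T cell genes averaged 0.26 (6 up), T cell receptor signalling genes 0.18 (6 up), regulatory T cell genes 0.12 (1 up) and cytotoxic genes 0.02 (1 up, 1 down). Non-classical monocyte genes averaged 0.39 (5 up, and adjusted p = 0.0451 with an estimated correlation), and classical monocyte genes -0.01 (1 down). MHC class II genes averaged 0.44 (2 up), dendritic cell genes 0.11 (4 up, 1 down) and basophil genes 0.21 (3 up). Cell cycle genes averaged 0.18 (9 up), ribosomal protein genes 0.41, and oxidative phosphorylation genes 0.26. Heme and iron genes averaged 0.12 (5 up, 1 down), circadian genes 0.03 (1 up, camera adjusted p = 0.192) and NADPH oxidase and trap genes 0.38 (5 up). IL-1 and inflammasome genes averaged -0.31 (3 down), glucocorticoid-responsive genes -0.28 (2 down), globin genes -1.04 (1 down) and erythroid genes -0.18 (0 called). The means of cytokine (-0.06, 2 up), Toll-like receptor (-0.09, 4 up), immediate early (-0.06, 1 up, 2 down), complement (-0.08, 1 up, 2 down), interferon (-0.03, 1 down) and brain and glial genes (-0.03, 3 up) lay below 0 without that library and above 0 with it.

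Some lists that passed camera at 7 days did not pass in each batch. In batch B these were not past it: T cell (mean 0.12, adjusted p = 0.197), T cell receptor signalling (0.05, 0.552), regulatory T cell (0.05, 0.894), MHC class II (0.27, 0.101) and non-classical monocyte genes (0.28, 0.0718). Nor were basophil (0.29, 0.0505), dendritic cell (0.15, 0.15), heme and iron (0.14, 0.372) and circadian genes (0.10, 0.552). In batch A the first 5 averaged 0.66, 0.48, 0.42, 0.76 and 0.77, or 0.37, 0.28, 0.17, 0.55 and 0.47 without the shallow library, and passed. The IL-1 and inflammasome list did not pass in batch A (-0.03, adjusted p = 0.235). Cell cycle genes without the shallow library did not pass there either (-0.04, adjusted p = 0.152), nor did glucocorticoid-responsive (-0.33, 0.0678) and circadian genes (-0.02, 0.157).

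In total 557 genes rose and 112 fell from baseline to 7 days. Without the shallow library 1685 rose and 522 fell, all 669 among them, and the median change of all genes moved to -0.16. TMM factors gave 383 up and 17 down, and raised the share up among called genes from 83.3% to 95.8%; edgeR called 1170 up and 174 down. Batch A alone gave 39 up and 3 down, batch B alone 68 up and 21 down, and 203 genes were called without the patient as a block. Several other granule and acute-phase genes did not pass at 7 days: MMP9 (-0.24, SE 0.236, adjusted p = 0.689, lower in 15 of 24), ARG1 (-0.52, SE 0.364, adjusted p = 0.501, lower in 16 of 24), HP (0.27, SE 0.3, adjusted p = 0.729, higher in 13 of 24), S100A12 (-0.17, SE 0.519, adjusted p = 0.926, lower in 16 of 24), CD177 (-0.13, SE 0.358, adjusted p = 0.917, lower in 14 of 24) and IL1R2 (-0.70, SE 0.268, adjusted p = 0.169, lower in 15 of 24). ARG1, the arginase of granulocytes, fell without the shallow library (-0.84, adjusted p = 0.0419). On simulated changes of the same design, the test found 28% of genes changed 1.5-fold and 52% of those changed 2-fold, so a missed threshold does not show an absent change.

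The union list of neutrophil degranulation genes gave a split answer. At 72 h its 151 measured genes averaged 0.22, with 5 up and 0 down (9 and 1 adjusted over the list alone, camera adjusted p = 2.26e-05, adjusted p = 0.58 with an estimated correlation). Without the shallow library the mean was 0.10, with 12 up and 2 down. CTSD, a lysosomal protease, and ALDH3B1, an aldehyde dehydrogenase, were among those 5 and rose by 0.45 (SE 0.118, adjusted p = 0.0482, higher in 21 of 26) and 0.46 (SE 0.114, adjusted p = 0.0355, higher in 21 of 26). At 7 days the mean was 0.25 and the median 0.08, with 24 up and 1 down (31 and 4 adjusted over the list alone, camera adjusted p = 0.00469, adjusted p = 0.768 with an estimated correlation, fry adjusted p = 0.349). The mean was 0.30 in batch A (camera adjusted p = 8.3e-05) and 0.16 in batch B, where camera placed the list down (adjusted p = 0.88). Leaving out the shallow library gave a mean in A of 0.10, below B, while camera, which ranks it against other genes, kept it up in A (adjusted p = 4.64e-06). Without the shallow library the mean at 7 days was 0.12 and the median 0.02, and 30 rose and 7 fell. The union's azurophil and specific lists, which share genes with the immature list, held 11 rising genes each and the vesicle list 0.

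Between 72 h and 7 days the same young neutrophil genes had higher means, though limma passed none. LTF was 1.33 higher at 7 days than at 72 h (SE 0.273, adjusted p = 0.09, higher in 21 of 23 patients), MPO 1.001 higher (SE 0.306, adjusted p = 1, higher in 18 of 23), OLFM4 1.16 higher (SE 0.354, adjusted p = 1, higher in 18 of 23), and LCN2 1.002 higher (SE 0.311, adjusted p = 1, higher in 17 of 23). MZB1 was 1.32 higher (adjusted p = 0.263, higher in 19 of 23), JCHAIN 1.48 higher (adjusted p = 0.771, higher in 20 of 23), and BIRC5, an inhibitor of apoptosis in dividing cells, 0.79 higher (adjusted p = 1, higher in 20 of 23). The limma count was 0 of 27864 genes with 535 at an unadjusted p under 0.05. Leaving out the shallow library gave 5 genes up and 0 down, each at an adjusted p of 0.0467: LTF, ITM2C, H3C8, H3C14 and IGHV3-9, the histone and immunoglobulin genes being named after their values were seen. edgeR called 7 up and 0 down: LTF (1.40, adjusted p = 0.0455, higher in 21 of 23), MZB1 (1.42, adjusted p = 0.0455), BIRC5 (0.78, adjusted p = 0.0455), H1-5, H3C8, H3C14 and IGHV3-9. Without the shallow library edgeR called 0. In simulated data 24% of 1.5-fold and 49% of 2-fold changes were found in this comparison.

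Immature neutrophil genes had the largest mean of any list from 72 h to 7 days. Their mean was 0.70 with 0 called over all genes and 19 up and 0 down adjusted over the list alone (camera adjusted p = 3.87e-38, and adjusted p = 0.00497 with an estimated correlation), 0.50 in batch A and 0.95 in batch B. Plasma cell genes averaged 0.60 with 0 called and 7 up and 0 down adjusted over the list alone (camera adjusted p = 1.88e-16, and adjusted p = 0.00497 with an estimated correlation), 0.65 in A and 0.55 in B. Mature neutrophil genes averaged -0.27 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 4.26e-15, adjusted p = 0.163 with an estimated correlation) and secretory vesicle genes -0.19 with 0 called (camera adjusted p = 2.94e-17, adjusted p = 0.287 with an estimated correlation). The degranulation union had a mean of 0.03, a median of -0.12 and a camera direction of down (adjusted p = 0.0212, adjusted p = 0.865 with an estimated correlation), with 0 called and 8 up and 0 down adjusted over the list alone. Within it the azurophil and specific lists averaged 0.31 (median 0.06, camera adjusted p = 1.17e-05, adjusted p = 0.416 with an estimated correlation) and 0.39 (camera adjusted p = 1.62e-12, adjusted p = 0.163 with an estimated correlation), and the gelatinase list -0.12 (camera adjusted p = 4.9e-06, adjusted p = 0.471 with an estimated correlation). The means within the union thus lay on both sides of 0, with 0 members called down by either count.

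Hsa-Mir-122_5p, the most abundant microRNA of hepatocytes, rose by 1.49 from baseline to 7 days (SE 0.347, limma adjusted p = 0.00982, higher in 19 of 24 patients), from 6.68 (SD 1.24, n = 27) to 8.27 (SD 1.32, n = 24), by 0.97 in batch A and 2.29 in batch B. Hsa-Mir-21_5p, induced in activated leukocytes, rose by 0.40 (SE 0.091, adjusted p = 0.00982, higher in 19 of 24), by 0.40 in A and 0.39 in B. Hsa-Mir-193-P1a_5p fell by 0.55 (SE 0.154, adjusted p = 0.0337, lower in 18 of 24) and Hsa-Mir-362-P3_3p by 0.34 (SE 0.101, adjusted p = 0.043, lower in 20 of 24). Hsa-Mir-154-P23_5p*, of the imprinted 14q32 cluster, fell by 1.12 (SE 0.302, adjusted p = 0.0273, lower in 19 of 24) but did not pass without the 4 shallowest small RNA libraries (-0.69, adjusted p = 0.0789). Hsa-Mir-744_5p, Hsa-Let-7-P2b2_3p* and Hsa-Mir-194-P1_3p* completed the 8 calls and are named after their values were seen; they fell by 0.56 (adjusted p = 0.0102, lower in 17 of 24), 1.63 (adjusted p = 0.0102, lower in 19 of 24) and 1.22 (adjusted p = 0.043, lower in 15 of 24). Without the 4 shallowest libraries Hsa-Mir-744_5p still fell (-0.57, adjusted p = 0.0181). Hsa-Let-7-P2b2_3p* (-1.26, adjusted p = 0.0517) and Hsa-Mir-194-P1_3p* (-0.90, adjusted p = 0.115) did not pass. Of the 8 calls 5 were kept.

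Of 263 microRNAs tested, 2 rose and 6 fell at 7 days by limma, and edgeR called 2 up and 14 down, a share up of 12.5% against 25%. Without the 4 shallowest libraries edgeR called 2 up and 4 down (33.3% up) and limma 2 up and 5 down. At 72 h 0 were called by limma (32 at an unadjusted p under 0.05) and 0 by edgeR (40), but 8 rose and 13 fell in batch A alone. Between 72 h and 7 days 0 were called by limma (9 at an unadjusted p under 0.05) and 0 by edgeR (2). The median change of all microRNAs at 72 h was -0.07 as deposited and -0.16 with TMM factors. In simulated data 30% of 1.5-fold and 70% of 2-fold microRNA changes were found at 7 days against baseline.

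Both microRNAs of the series title were lower on average after baseline without passing over all microRNAs. Hsa-Mir-3613_5p was 0.75 lower at 72 h (SE 0.38, limma adjusted p = 0.395, lower in 14 of 26 patients) and 0.76 lower at 7 days (SE 0.392, adjusted p = 0.253, lower in 16 of 24), and 0.02 lower at 7 days than at 72 h (adjusted p = 0.996). The drop at 7 days was 0.37 in batch A and 1.40 in batch B, whose baseline medians were 10.9 and 140.5. Hsa-Mir-3690_5p was 0.42 lower at 72 h (SE 0.241, adjusted p = 0.478, lower in 14 of 26) and 0.51 lower at 7 days (SE 0.248, adjusted p = 0.215, lower in 15 of 24); at 7 days it was 0.86 lower in A and 0.02 higher in B. Hsa-Mir-3613_3p*, the other strand of that hairpin, was 0.10 higher at 72 h (adjusted p = 0.945) and 0.04 higher at 7 days (adjusted p = 0.98), and 6 of 10 baseline libraries of batch B held no read of it. Without the 4 shallowest libraries Hsa-Mir-3613_5p was 0.85 lower at 7 days and Hsa-Mir-3690_5p 0.65 lower, each at an adjusted p of 0.115 over all microRNAs. Adjusted over the title list alone, 2 of its 3 members then fell, against 0 with all libraries.

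None of the 10 microRNA lists passed camera in any comparison; the lowest adjusted p values were 0.439 at 72 h, 0.176 between 72 h and 7 days and 0.312 at 7 days. Means at 7 days against baseline were -0.41 for the title microRNAs, -0.09 for myeloid, 0.11 for lymphocyte, -0.20 for erythroid and 0.05 for platelet microRNAs. They were -0.21 for the 14q32 cluster, 0.14 for inflammation, -0.04 for let-7 and 0.05 for the miR-17-92 family. Of their members, Hsa-Mir-21_5p and Hsa-Mir-154-P23_5p* passed over all microRNAs; adjusted over the list alone, 1 of the erythroid, 1 of the 14q32 and 1 of the platelet members fell and 1 of the platelet and 1 of the inflammation members rose. Brain-enriched microRNAs (4 measured) averaged -0.27 at 7 days and -0.30 at 72 h, and passed downward by fry (fry adjusted p = 0.0281 and 0.031) but not by camera, which also placed them down (adjusted p = 0.312 and 0.439). Without the 4 shallowest libraries the fry values were 0.0467 and 0.06. Erythroid microRNAs then passed fry at 7 days (mean -0.32, fry adjusted p = 0.00883).

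Per patient, a larger rise of the degranulation score at 7 days went with a larger drop of Hsa-Mir-3613_5p by rank. Among 24 patients Spearman rho was -0.637 (permutation p = 0.00106, adjusted p = 0.00954 over 9 relations) and Pearson r was -0.455 (permutation p = 0.0374, adjusted p = 0.337). Without the 2 patients farthest on the microRNA axis r was -0.638 (n = 22, adjusted p = 0.00279), and without shallow libraries -0.697 (n = 20, adjusted p = 0.00369). Within batches r was -0.741 in A (n = 14, adjusted p = 0.0116) and -0.389 in B (n = 10, adjusted p = 0.799). By rank the relation passed in neither (rho -0.596 in A, adjusted p = 0.123, and -0.539 in B, adjusted p = 0.518). At 72 h, r was -0.234 (n = 26, permutation p = 0.222, adjusted p = 0.499) and rho -0.433 (permutation p = 0.0281, adjusted p = 0.126). By rank the 72 h relation passed without the 2 farthest patients (rho -0.532, adjusted p = 0.0363), in batch A (-0.674, adjusted p = 0.0358) and without shallow libraries (-0.506, adjusted p = 0.0396). It did not pass in batch B (-0.1, adjusted p = 0.892). Hsa-Mir-3690_5p gave r of -0.304 (n = 24, permutation p = 0.15, adjusted p = 0.45) and rho of -0.252 (permutation p = 0.234, adjusted p = 0.355) at 7 days, -0.401 in A and -0.045 in B. Hsa-Mir-3613_3p* gave r of -0.062 at 7 days, and the 9 relations share libraries.

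**Figure D3:**
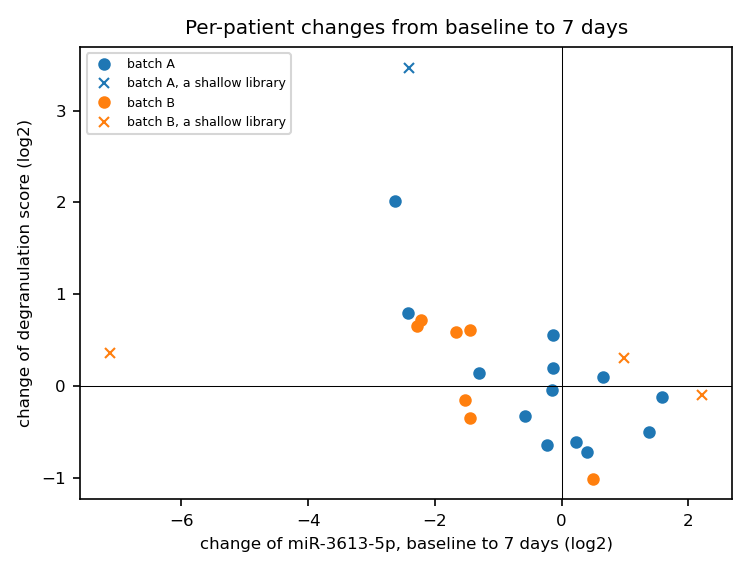
Change of the degranulation score against change of miR-3613-5p from baseline to 7 days in each patient. Colours mark the batches and crosses patients with a shallow library.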

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

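Between 72 h and 7 days, 21 gene lists passed camera at the preset correlation while limma called 0 genes. Immature neutrophil genes (mean 0.70, camera adjusted p = 3.87e-38) and plasma cell genes (mean 0.60, adjusted p = 1.88e-16) kept an adjusted p = 0.00497 with an estimated correlation, unlike the other 19. By fry the adjusted p was 0.0555 for both, and 0.0105 and 0.00255 without the shallow library. Upward lists by camera were specific granule genes (mean 0.39, adjusted p = 1.62e-12, or 0.163 with an estimated correlation), cell cycle genes (mean 0.30, adjusted p = 2.44e-13, or 0.163 with an estimated correlation), eosinophil genes (mean 0.38, adjusted p = 7.47e-08, or 0.251 with an estimated correlation) and azurophil granule genes (mean 0.31, adjusted p = 1.17e-05, or 0.416 with an estimated correlation). Platelet genes (mean 0.17, adjusted p = 2.71e-05, or 0.554 with an estimated correlation), basophil genes (mean 0.21, adjusted p = 0.005, or 0.514 with an estimated correlation), dendritic cell genes (mean 0.11, adjusted p = 0.0409, or 0.583 with an estimated correlation) and ribosomal protein genes (mean 0.08, adjusted p = 0.0265, or 0.865 with an estimated correlation) were also up.

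Downward lists were secretory vesicle genes (mean -0.19, camera adjusted p = 2.94e-17, adjusted p = 0.287 with an estimated correlation), mature neutrophil genes (mean -0.27, adjusted p = 4.26e-15, adjusted p = 0.163 with an estimated correlation), Toll-like receptor genes (mean -0.17, adjusted p = 3.05e-08, adjusted p = 0.286 with an estimated correlation) and IL-1 and inflammasome genes (mean -0.21, adjusted p = 4.24e-08, adjusted p = 0.163 with an estimated correlation). Gelatinase granule genes (mean -0.12, adjusted p = 4.9e-06, adjusted p = 0.471 with an estimated correlation), cytokine and NF-kB genes (mean -0.12, adjusted p = 4.63e-05, adjusted p = 0.287 with an estimated correlation) and classical monocyte genes (mean -0.16, adjusted p = 6.43e-05, adjusted p = 0.514 with an estimated correlation) were lower as well. Smaller shifts were those of immediate early genes (mean -0.08, adjusted p = 0.00266, adjusted p = 0.514 with an estimated correlation), erythroid genes (mean -0.06, adjusted p = 0.013, adjusted p = 0.865 with an estimated correlation), complement genes (mean -0.05, adjusted p = 0.0204, adjusted p = 0.774 with an estimated correlation) and the degranulation union (mean 0.03 against a median of -0.12, adjusted p = 0.0212, adjusted p = 0.865 with an estimated correlation). Leaving out the shallow library ended the call at the preset correlation for dendritic cell (adjusted p = 0.0679), ribosomal protein (0.0919) and complement genes (0.0557).

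From baseline to 7 days the degranulation union passed a batch interaction (camera adjusted p = 0.00212, means 0.30 in A and 0.16 in B). Only the preset correlation was used. The mean of A was 0.10 without the shallow library, so the order of the means turned, and the interaction still passed (adjusted p = 3.7e-05). It was not alone: 28 of 36 lists passed the same interaction test at 7 days, 22 at 72 h and 14 from 72 h to 7 days, with 0 genes changed differently by limma in each. At 72 h, 7 microRNAs changed differently in A and B by limma, among them Hsa-Mir-423_3p and Hsa-Mir-374-P1_5p, and only Hsa-Mir-374-P1_5p did without the 4 shallowest small RNA libraries; these names were chosen after their values were seen. The cause of any batch difference was not tested.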

How the results depend on the processing

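The count of genes called at 72 h (207) rested on the shallow baseline library and on how the spread was modelled. It was 1575 without that library, 8583 with array weights (2443 up, 6140 down), 6996 with the mature neutrophil score as a covariate (4303 up, 2693 down) and 17805 with both that score and the library left out (5161 up, 12644 down). Falls thus outnumbered rises with array weights and in the last of these fits, against a share up of 91.3% with all libraries. It was 325 with a pseudocount of 5, 339 with a filter at a mean of 50, 95 with upper-quartile scaling and 3214 with TMM scaling without the library. Complete cases gave 82, the libraries of both time points alone 48, batch A 21, batch A without the library 819, and batch B 1. edgeR called 1870, and 1800 without the library. Leaving out a patient at a time gave 93 to 1436, with 424 the next highest.

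From 72 h to 7 days limma called 0 genes, against 44 with array weights, 5 without the shallow library, 2 (IGKC and JCHAIN, named after their values were seen) with the neutrophil score and without that library, and 7 by edgeR. Leaving out patients gave 0 to 3. From baseline to 7 days 669 were called, against 1120 with a pseudocount of 5, 400 with TMM, 384 with upper-quartile scaling, 319 in complete cases, 121 with both time points alone, 42 in batch A and 89 in batch B. Array weights gave 3521, a share up of 59.6% against 83.3%, the neutrophil score 8710 (5820 up, 2890 down), the library left out 2207 and TMM without the library 2043. The score without the library gave 18293, of which 5138 were up and 13155 down. Batch A without the library gave 660 (545 up, 115 down), and edgeR 1344 and, without the library, 1325. Patients left out in turn gave 369 to 2204, with 850 next.

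The pairing by patient mattered for counts. Without the replicate block 22 genes were called at 72 h, 203 at 7 days and 1 microRNA, Hsa-Mir-122_5p, at 7 days. Without it the neutrophil degranulation list test, 7 day vs baseline, no longer passed camera (adjusted p = 0.0816), miR-3613-5p from 72 h to 7 days moved to 0.096, and the list test, ribosomal protein genes, 7 day vs 72 h, turned down (adjusted p = 0.357); with the patient as a random effect block these last values were 0.046 and, still downward, an adjusted p of 0.883.

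In the neutrophil degranulation list test, 72 h vs baseline, the direction held in every fit, with patients left out giving camera adjusted p values from 2.5e-07 to 0.00265, but did not pass with an estimated correlation (0.58) or by fry (0.263). In the neutrophil degranulation list test, 7 day vs 72 h, the downward call was lost with a filter of 50 (0.146), TMM (0.211), batch A (0.567), TMM without the library (0.383), batch A without the library (0.905), edgeR (0.205, 0.177 without the library), an estimated correlation (0.865) and fry (0.949). It turned up with the mature neutrophil score as a covariate (1.22e-11, 4.81e-19 without the library), and patients left out gave 1.53e-09 to 0.838. In the neutrophil degranulation list test, 7 day vs baseline, the upward call was lost with a filter of 50 (0.143), complete cases (0.128), array weights (0.186), an estimated correlation (0.768) and fry (0.349), turned down in batch B (0.882), and ranged from 1.01e-05 to 0.388 with patients left out, the value of 0.388 being a turn down.

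Several other lists turned direction between batches, and more did with the neutrophil score. From baseline to 7 days batch B turned down gelatinase granule (adjusted p = 0.0105), classical monocyte (0.00425), interferon (2.53e-07), cytokine (0.00172) and Toll-like receptor genes (5.35e-05), and batch A turned up secretory vesicle (0.603) and globin genes (0.482), the latter down again without the shallow library (0.978). From 72 h to 7 days interferon genes turned up in batch A (1.7e-06), and ribosomal genes down in batch B (0.977) and with array weights (0.94). With a single patient left out, the list test, interferon-stimulated genes, 7 day vs 72 h, gave 0.000251 to 0.826 with a turn up at 0.000262, and the list test, ribosomal protein genes, 7 day vs 72 h, gave 2.21e-07 to 0.64 with a turn down at 0.499. The list test, neutrophil gelatinase (tertiary) granule proteins, 7 day vs baseline, gave 0.0392, a turn down, to 0.976. The neutrophil score as a covariate was planned for the counts and the degranulation list only, and its effect on the other 35 lists was restricted to these sums after it was seen. It turned 0 of them at 72 h, 9 from 72 h to 7 days and 5 at 7 days, and 3, 14 and 7 without the library. TMM without the library turned 0 in each comparison and batch A without it 0, 1 and 2. This covariate is itself a blood measure that changes with time, so those fits ask another question.

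For microRNAs the 0 calls at 72 h became 21 in batch A and 15 with array weights. The 8 calls at 7 days became 14 with upper-quartile scaling, 22 in batch A, 1 in batch B, 4 with the libraries of both time points alone and 16 by edgeR; array weights gave 12. Patients left out gave 0 to 0, 0 to 0 and 4 to 16. The change of miR-3690-5p was 0.161 at 72 h and 0.02 at 7 days in batch B, and that of miR-3613-3p -0.323 and -0.334. From 72 h to 7 days miR-3613-3p moved to 0.009 with TMM, and miR-3613-5p to 0.016 with a pseudocount of 0.5, 0.054 with TMM, 0.066 in complete cases, 0.066 with the libraries of both time points alone and 0.312 in batch B. With patients left out the ranges at 72 h, from 72 h to 7 days and at 7 days were -0.844 to -0.497, -0.351 to 0.095 and -0.91 to -0.503 for miR-3613-5p. They were -0.503 to -0.27, -0.235 to 0.008 and -0.609 to -0.417 for miR-3690-5p, and -0.092 to 0.263, -0.317 to 0.150 and -0.212 to 0.272 for miR-3613-3p.

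The correlation of miR-3613-5p with the degranulation score from baseline to 7 days (r = -0.455) was -0.638 without the 2 farthest patients, -0.741 in batch A and -0.697 without shallow libraries, each past the adjusted threshold. By rank it passed in neither batch, and at 72 h in batch A, without the 2 farthest and without shallow libraries. At 72 h miR-3613-3p gave -0.869 in batch B (n = 9, exact p = 0.0037, adjusted p = 0.0333), 0.101 in batch A and -0.596 without shallow libraries (adjusted p = 0.00707). miR-3690-5p moved to 0.169 in batch B at 72 h and to -0.025 in batch A from 72 h to 7 days. Of 103 named features called, all 98 genes kept their call without the shallow library, and of the 103, 94 kept it with edgeR, 71 with TMM, 37 without the block, 26 in batch B and 17 in batch A, and 0 turned direction.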

Other observations

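Replication-dependent histone genes, whose transcripts lack the usual poly(A) tail and mark cells copying their DNA, were higher at 7 days. Of 59 such genes tested, 25 rose and 0 fell from baseline to 7 days, with a mean change of 0.88 and 57 above 0. The group was chosen after the values were seen, and its camera p was 7.78e-34, or 0.00727 with an estimated correlation. Without the shallow library 31 rose. At 72 h 2 rose with a mean of 0.47 (p = 0.123 with an estimated correlation), and from 72 h to 7 days the mean was 0.42 with 0 called (p = 0.0159 with an estimated correlation). H3C8 was 1.32 higher at 7 days than at 72 h (limma adjusted p = 0.09, higher in 21 of 23 patients), and copies such as H3C14 and H3C15 share reads and are uncertain singly.

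The time points were relabelled within patients 100 times, the true labels included, to ask whether chance could give as many calls. At 72 h 1 of 100 labelings, the true one, gave 207 genes, and the highest other gave 2, so chance is unlikely. At 7 days 2 of 100 reached the true count of 669, fewer than the 5 set beforehand as the limit for chance. The highest other labeling called 14452 genes for a reason that was not tested, and without the shallow library that fell to 1442 against a true 2207 (1 of 100). Without that library 72 h gave 1575 against 0 (1 of 100) and 72 h to 7 days 5 against 0 (1 of 100). With all libraries the true count from 72 h to 7 days was 0 genes, as it was for microRNAs at 72 h and from 72 h to 7 days. Every labeling reaches a count of 0 (100 of 100, 100 of 100 and 100 of 100), so the test decided nothing for these 3. For microRNAs at 7 days 1 of 100 reached 8, with 0 the highest other, so chance is unlikely there.

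The higher granule genes of immature neutrophils at 7 days were weighed with 3 tests, all chosen after the result was seen. The shallow library was excluded as the source, since 18 members were called without it and 17 with it. From 72 h to 7 days the immature score rose 0.649 more than the T cell score (SE 0.213). With T cells uncounted, a lower mature neutrophil share stays open. A constant offset between batches cannot make a rise within patients, each of whom lay in 1 batch. Whether the rise rested on batch B alone cannot be told, because without the shallow library the lower batch mean from baseline to 7 days was 0.464 (SE 0.234, batch A, 13 patients) against 1.64 in batch B (SE 0.323, 10 patients). In batch A 2 of the 25 members were called, and camera at the preset correlation passed (adjusted p = 5.96e-08). The pattern may reflect release of young neutrophils from the marrow, which was not tested because no cell counts were used.

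RPS29 took a median of 20.7% of the messenger RNA reads, and both tests of its source were written before their values were seen, while a condition on the spread of r was added after. RN7SL1, the 7SL RNA of the signal recognition particle (chromosome 14, 49586580 to 49586878), lies inside the span of RPS29 (49570988 to 49598710) and had a mean value of 0. Over 76 libraries RPS29 followed the small structured RNAs RN7SK, RMRP and RPPH1 with r of 0.532 (95% interval 0.348 to 0.676), as reads of 7SL RNA assigned to RPS29 would. Its r with 53 other ribosomal protein genes was 0.286 (0.065 to 0.481), which leaves the messenger RNA itself undecided, so the RPS29 value is uncertain and may be largely 7SL RNA.

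The rise of Hsa-Mir-122_5p at 7 days was weighed with a depth test chosen after the result was seen and a liver test written before, whose condition on spread and baseline level was added after. The 4 shallowest small RNA libraries were not its source, since the change was 1.45 without them against 1.49 with them. An effect of depth among the other libraries was not tested. Release from liver cells could not be decided: the tested forms of miR-192 and miR-194 changed by a mean of 0.115 (SE 0.0540), but both are also plentiful in blood cells at baseline and could hide a small release. The source of the rise may be the liver or the course of treatment, and neither was tested further.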
